A study of Mus musculus with 6 samples.

How the data were processed

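RNA from mouse liver was measured in 6 libraries, 3 from mice trained by running and 3 from sedentary mice. Per the labels, the mice were perfused with saline before the liver was taken, RNA was extracted with TRIzol, and libraries were read in pairs on a DNBseq instrument. Per the labels' protocols, reads of low quality, reads with many undetermined bases and short reads were removed before counting. Per the submitters' processing notes, the build was GRCm38.p6 and the tools included cutadapt, featureCounts and MultiQC. Their versions, the aligner and the annotation are not given in the sources used here, nor is it stated whether counting used strand.

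Per the file headers, the deposited table held 3 values for each gene and library, namely a read count, an FPKM (fragments per kilobase of transcript, scaled by library size) and a TPM, which is scaled to a fixed library sum. The deposited read counts were estimated counts, since 1165 of the 16123 genes had a count that was not whole in at least 1 library. The authors' FPKM values were taken as given, and their sums lay between 776650 and 800330 per library. The 6 columns of averages in the table were not used. Reads shared between near-identical genes can explain counts that are not whole, and 666 genes with such counts were among those tested. The FPKM and the count of a gene need not move by the same factor, because the transcript length behind an FPKM can differ between libraries. For Crybb3 the mean count went from 114 to 13.3 while the mean FPKM went from 11.9 to 0.730.

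Each column was matched to its sample through the description in the labels, and each sample was put in its group by its treatment label. Gene identifiers were looked up in the RefSeq table of GRCm38.p6 by gene ID, where 16080 of the 16123 were found, 16000 of them protein-coding. Coordinates are those of that table, counted from 1. Mitochondrially encoded genes were not analysed here.

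Counts were rounded to whole numbers and compared with edgeR 4.0.16 in R 4.3.3. The fit used TMM scaling, estimated dispersions and the quasi-likelihood F test of exercise against sedentary, two-sided and without covariates. Genes with a mean FPKM of at least 1 over the 6 libraries were tested, 10266 in all. P-values were adjusted by the Benjamini-Hochberg method over these genes, with a threshold of 0.05. Log2 fold changes are exercise minus sedentary with edgeR's prior count of 0.125. Their standard error is the log2 fold change divided by the square root of F. Unless an alternative is named, fold changes come from TMM-scaled counts and can differ from the ratio of the FPKM means beside them. The TMM factors were 0.972 to 0.977 in the sedentary and 1.03 in the exercise libraries. This scaling set exercise values lower against sedentary ones than FPKM did. The design written before the data were examined named limma on log2(FPKM + 1) for a table of FPKM alone and edgeR for a table with raw counts. The table held counts, so edgeR was used, and the limma fit is given as an alternative.

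Gene lists, 45 in number, were fixed before the data were examined. They covered metabolic pathways, stress and inflammatory responses, sex-biased and zonated liver genes, and markers of the cell types that liver tissue or its surroundings can hold. Lists with at least 5 tested genes, 37 of them, were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry. Adjustment was over the 37 lists. The genes named in the text were chosen by a rule fixed at the same time. It took the 15 highest and the 15 lowest log2 fold changes among genes past the threshold whose groups did not overlap, up to 6 members of each described list with the smallest p, and 8 enzymes close to the question of the study (Ldha, Ldhb, Ep300, Sirt3, Pck1, Cpt1a, Fasn and Cyp7a1). Genes named outside the rule are said to be so.

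Library totals were between 17941303 and 18371949 counts. A gene without reads in a library was given a floor of 3 counts in that library for a bound on its fold change, and floors and intervals cover counting error only. Intervals of shares are exact binomial intervals at 95%. Libraries were compared pair by pair with a chi-square of their scaled counts against counting noise, over genes with at least 20 reads in the pair. The separation of the groups was tested with an exact permutation test over the 10 splits of the 6 libraries into 3 and 3.

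The test was checked on simulated data drawn from the real means, library sizes and dispersions, with 50 of the 10266 genes changed at each of 4 sizes. For exercise against sedentary, edgeR recovered 70% of the genes changed 1.25-fold, 90% of those changed 1.5-fold, 94% of those changed 2-fold and 100% of those changed 4-fold. Of its calls, 5.35% were unchanged genes. In simulated lists, camera called the changed list and 1 of 20 unchanged lists. These rates hold for the spread between these libraries and for few changed genes. They do not describe a wider spread between animals or a change of many genes at once.

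The alternatives fixed before the data were examined were other pseudocounts, filters, scalings and variance models, a replicate block, and leaving out each library in turn. Alternatives added after seeing the data were DESeq2 1.42.0, limma on log2(FPKM + 1), edgeR without TMM, edgeR with an offset for gene length and GC content, a test against a 1.2-fold change, and a comparison of the summed counts of each group with an assumed biological variation. The length and GC offset could be computed for 98.7% of the tested genes. Camera as run here did not use limma's variance trend or robust option, so limma fits differing in these alone gave the same list results. Counts of alternatives in which a list passed are therefore not counts of separate checks.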

Results

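Messenger RNA was measured in the livers of mice that ran on a treadmill and of mice that stayed sedentary, to ask how moderate exercise changes liver metabolism in a study that also covered protein lactylation. The running distance was 22 km per mouse over 6 weeks, and the liver was taken 24 h after the last training. Each group had 3 libraries, which the design text describes as 3 mice per group. The exercise libraries held 18067298, 17941303 and 18019044 counts and the sedentary libraries 18371949, 18164094 and 18285233. Between 14683 and 14804 of the 16123 listed genes had reads in a library. The 20 most abundant genes took 29.1% to 29.4% of the counts in the sedentary libraries and 26.8% to 27.2% in the exercise libraries.

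Libraries of 1 group were close to identical. Among genes with 20 to fewer than 2000 reads in a pair, the mean chi-square per gene was 1.13 to 1.21 for the 6 pairs within a group, where counting noise alone gives 1, and 4.23 to 4.36 for the 9 pairs between groups. Among genes with 2000 reads or more it was 2.62 to 3.46 within groups and 152 to 171 between groups. The common biological coefficient of variation was 1.84%. Spearman's rho over the tested genes was 0.996 within groups and 0.987 between groups, and the groups separated more than in any of the 9 other splits (exact permutation p = 0.1, the smallest that 10 splits allow). The p-values that follow measure the spread between these libraries alone.

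**Figure D1:**
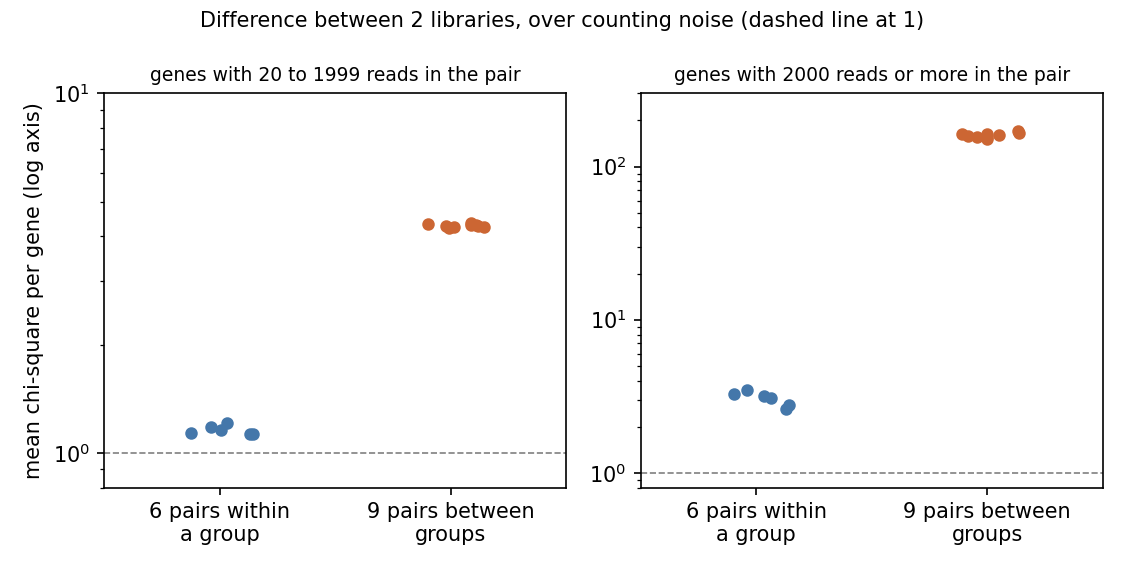
Mean chi-square per gene for each pair of libraries (log axis, no unit), with genes of 20 to fewer than 2000 reads on the left and of 2000 reads or more on the right. Each point is 1 pair, and the dashed line at 1 marks counting noise. The 6 pairs within a group lie at 1.13 to 1.21 and at 2.62 to 3.46, and the 9 pairs between groups at 4.23 to 4.36 and at 152 to 171.

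Among the largest changes between exercise and sedentary livers were falls of inflammation-linked secreted proteins. The serum amyloid A gene Saa2 (gene ID 20209, chromosome 7, 46751833 to 46754313 in GRCm38.p6) fell 104-fold by TMM-scaled counts. It was at 3150 ± 67.5 FPKM in sedentary and 31.4 ± 1.98 FPKM in exercise libraries (SD, n = 3). Saa1 fell 44.7-fold, Lcn2, which encodes lipocalin 2, fell 55.3-fold and Orm2, an orosomucoid, fell 17.3-fold. The metallothioneins Mt2 and Mt1, which bind zinc and copper, fell 11.8-fold and 4.76-fold. The largest rises were of the chaperone Hspa1a and of Cyp4a14, a fatty acid omega-hydroxylase (gene ID 13119, chromosome 4, 115486200 to 115496158). Hspa1a rose 8.77-fold on mean counts of 17.2 in sedentary and 156 in exercise libraries. Cyp4a14 went from 27.2 ± 0.829 to 248 ± 7.36 FPKM (SD, n = 3) and rose 8.67-fold by TMM-scaled counts.

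In all, 3913 of the 10266 tested genes passed the threshold (edgeR, adjusted over all tested genes), 1961 higher and 1952 lower in exercise. Most of these changes were small, with a median absolute log2 fold change of 0.24. Only 94 genes changed at least 2-fold, 19 of them higher and 75 lower. By the deposited FPKM the groups did not overlap in 51.0% of the tested genes, where chance gives 10%. Of these 5231 genes 3308 passed the threshold. The FPKM leaned higher in exercise (median log2 fold change 0.0626 by limma), which can add to that share. The balance of directions depended on the scaling and the test. It was 3537 higher to 1203 lower without TMM, 3716 to 915 on the TPM scale, 2918 to 1429 with totals taken without the 20 most abundant genes, and 2868 to 1099 with limma on log2(FPKM + 1), but 2130 to 1821 with the median of ratios and 1727 to 1465 after quantile normalization. Other tests gave other counts. DESeq2 called 2512 genes, a test against a 1.2-fold change called 653, and a comparison of 1 summed library per group called 179 genes at an assumed biological variation of 0.1 and 23 at 0.2.

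Among the other genes with the largest rises were Hspa1b (4.03-fold), the hepatokine gene Fgf21 (4.02-fold, mean counts 10.7 and 45.0), the immediate-early gene Fos (3.40-fold, mean counts 21.3 and 75.7) and Cyp4a10 (3.11-fold). Creld2 and Syvn1, which act in the endoplasmic reticulum, rose 2.43-fold and 2.38-fold. Angptl8, a secreted regulator of lipoprotein lipase, rose 2.31-fold, the lipid droplet protein gene Plin4 2.33-fold, the transcriptional repressor gene Zbtb16 2.49-fold and Csad, an enzyme of taurine synthesis, 2.26-fold. Acta2, the smooth muscle actin gene, rose 2.49-fold on mean counts of 18.3 and 47.7. The meiotic gene Rec114 rose 4.16-fold on mean counts of 6 and 26.3. Cox7a1 rose 2.82-fold on mean counts of only 3.67 and 11. The log2 fold change of Cox7a1 was 1.14 without exercise replicate 1 (adjusted p = 0.12), and DESeq2 gave it an adjusted p of 0.0834.

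Among the other genes with the largest falls were Prtn3, a protease of neutrophil granules (9.23-fold), the crystallin gene Crybb3 (8.82-fold), Cish, a feedback inhibitor of cytokine signalling (8.17-fold), and Moxd1 (7.97-fold). Onecut1, a hepatocyte transcription factor, fell 6.65-fold, Saa3 7.89-fold, Orm3 5.48-fold and Nrep 3.85-fold. The pancreatic amylase gene Amy2a5 had 53, 55 and 62 reads in the sedentary libraries and none in the exercise libraries, so it was at least 19.6-fold lower against a floor of 3 counts per library. Summed over all pancreatic acinar genes of the list, the sedentary libraries had 299, 312 and 293 reads and the exercise libraries 118, 124 and 126. Of these genes, Amy2a5 and 10 others, picked because the exercise libraries had no reads of them and every sedentary library did, summed to 115, 135 and 109 reads in the sedentary libraries. All 15 of these most lowered genes stayed past the threshold at an assumed variation of 0.2, as did 5 of the 15 most raised. Counts of Hspa1a, Hspa1b, Saa1, Saa2 and Cyp4a10 were not whole in at least 1 library. Reads shared with near-identical genes can explain this, which was not tested, so the split of their reads may be uncertain.

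**Figure D2:**
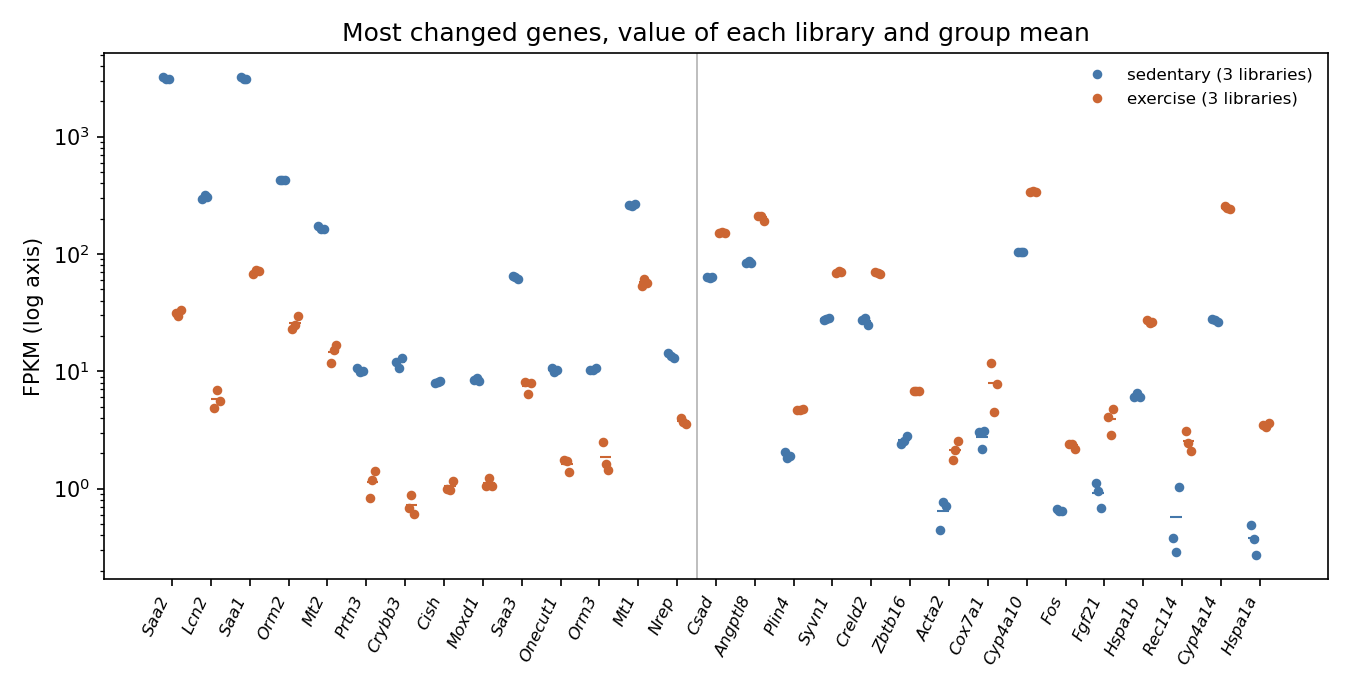
FPKM (log axis) of the genes with the largest falls (left of the grey line) and the largest rises (right of it), without Amy2a5, which is at 0 in the exercise libraries. Points are the 3 libraries of each group and short lines the group means. For each gene the 2 groups do not overlap, as for Saa2 at means of 3150 and 31.4 FPKM and Cyp4a14 at 27.2 and 248 FPKM.

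Acute phase genes, whose products are secreted by the liver in inflammation, fell almost throughout. Of 28 tested members 26 fell, none rose and 2 did not pass the test, with a median log2 fold change of −0.78 (camera adjusted p = 5.49e-252, and adjusted p = 0.00162 with an estimated correlation). Beyond the genes above, hemopexin (Hpx) went from 5498 ± 79.4 to 2812 ± 33.5 FPKM (SD, n = 3). By TMM-scaled counts Hpx fell 2.06-fold and haptoglobin (Hp) fell 1.84-fold. Interferon-stimulated genes fell as well, 29 of 35 lower and none higher, with a median of −0.52 (adjusted p = 6.04e-09, and 0.0235 with an estimated correlation). Gbp6 fell 1.88-fold, and Ifih1, a sensor of viral RNA, fell as well (log2 fold change −0.62). Adjusted over the list alone, 26 acute phase and 31 interferon-stimulated genes fell.

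Markers of Kupffer cells and other macrophages were lower in the same libraries, with 12 of 17 lower, none higher and a median of −0.26 (adjusted p = 0.00029). That call was lost with an estimated correlation (adjusted p = 0.099). Marco fell 1.89-fold and Mpeg1 fell 1.59-fold. Of 5 tested neutrophil markers Lcn2 fell, Il1b rose and 3 did not pass, with a median of −0.35 and a mean of −1.21 (adjusted p = 2.23e-11, and 0.0136 with an estimated correlation), which was −0.13 without sedentary replicate 1 and −0.51 without sedentary replicate 2. Lcn2, at a log2 fold change of −5.79, is the only member that fell, and stands in the acute phase list too. The neutrophil call held in 12 of the 20 alternatives that could test it, and ended without a filter on low genes (adjusted p = 0.0603), with limma on log2(FPKM + 1) (0.081) and with quantile normalization (0.219), among others. MHC class II genes had 6 of 8 members lower and none higher (median −0.28), and the list did not pass (adjusted p = 0.0748). It passed in 10 of 21 alternatives, among them limma on log2(FPKM + 1) (0.000872) and the fit without exercise replicate 2 (0.0485).

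Genes responsive to the fatty acid receptor PPAR-alpha rose, with 17 of 26 higher, 3 lower and 6 not past the test, and a median of 0.30 (adjusted p = 2.47e-23, and 0.00503 with an estimated correlation). Besides Cyp4a14, Cyp4a10 and Fgf21, the peroxisomal beta-oxidation genes Acaa1b and Ehhadh rose 1.58-fold and 1.52-fold, and the thioesterase gene Acot1 rose 1.97-fold. Fatty acid oxidation genes, which share Acaa1b, Ehhadh and Cpt1a with that list, also rose, 22 of 30 higher and 1 lower, with a median of 0.14 (adjusted p = 6.16e-09, and 0.0305 with an estimated correlation). The lower member was Cpt1a, the entry enzyme of mitochondrial oxidation, at a log2 fold change of −0.14 (SE 0.02, adjusted p = 4.35e-06). The log2 fold change of Cpt1a was −0.03 on the TPM scale, where it did not pass (adjusted p = 0.411), nor did it in most limma fits. Of 10 ketone body genes 6 rose and none fell, with a median of 0.16 (adjusted p = 0.0139). That call was lost with an estimated correlation (adjusted p = 0.123), although the estimate, −0.103, lay below the preset one. Adjusted over the list alone, 18 PPAR-alpha-responsive genes rose and 3 fell, and the counts of the other lists of this paragraph were the same.

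Genes of cholesterol synthesis and uptake fell, with 22 of 26 lower, 1 higher and 3 not past the test, and a median of −0.35 (adjusted p = 3.93e-21, and 0.00503 with an estimated correlation). Hmgcs1, Dhcr7 and Msmo1 fell 1.75-fold, 1.76-fold and 1.62-fold. Adjusted over the list alone, the same number of members fell. Fatty acid and triglyceride synthesis did not move 1 way, with 10 of 25 members higher, 9 lower and a median of 0.04 (adjusted p = 0.121). In this list the desaturase gene Scd1 rose from 585 ± 3.70 to 1055 ± 5.11 FPKM (SD, n = 3), Me1 rose 1.57-fold and Fasn, the fatty acid synthase gene, rose 1.21-fold, while Aacs fell 2.13-fold and Thrsp fell 1.61-fold. Bile acid genes had 15 of 24 members higher and 6 lower (median 0.12, mean −0.01, adjusted p = 0.398), with Cyp7a1, the rate-limiting enzyme of bile acid synthesis, falling 2.12-fold. These last 2 lists passed without TMM (adjusted p = 0.0108 and 0.0484), the first also with totals taken without the 20 most abundant genes (0.0279) and the second without a filter (0.00678).

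Stress response genes rose in 2 lists. The unfolded protein and integrated stress response had 19 of 27 members higher, 6 lower and 2 not past the test, with a median of 0.30 (adjusted p = 6.6e-15, and 0.00758 with an estimated correlation). Hyou1 and Hspa5, chaperones of the endoplasmic reticulum, rose 1.84-fold and 1.75-fold, as Creld2 and Syvn1 did above. Heat shock genes had 13 of 20 members higher and none lower, with a median of 0.26 (adjusted p = 8.04e-10, and 0.0136 with an estimated correlation), among them Hsph1 (1.71-fold) beside Hspa1a and Hspa1b. Adjusted over the list alone, 13 heat shock genes rose and 1 fell. Antioxidant and xenobiotic enzymes were called higher, with 12 of 30 and 16 of 30 members higher, 5 and 6 lower, and medians of 0.03 and 0.09 (adjusted p = 0.0214 and 0.0193). Both calls were lost with an estimated correlation (adjusted p = 0.295 and 0.262), and the first at a mean FPKM of at least 5 (0.0558).

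**Figure D3:**
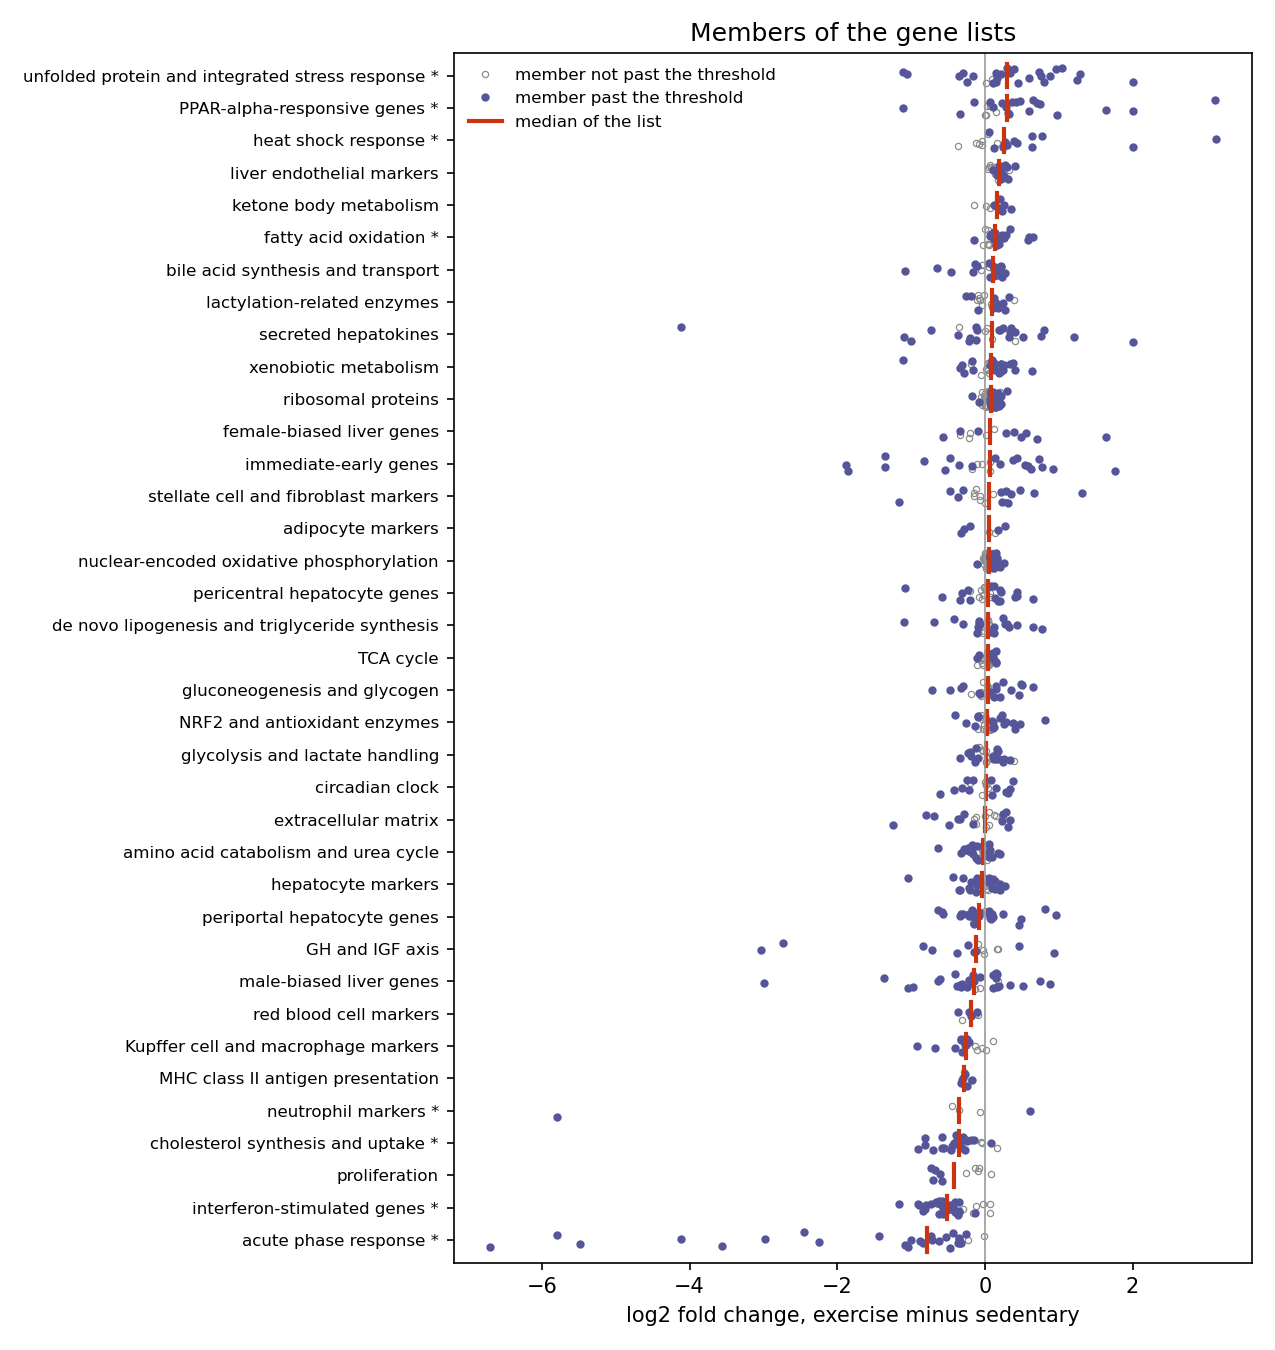
Log2 fold change, exercise minus sedentary, of the members of the 37 tested lists, ordered by the median of each list (red bar). Filled points passed the threshold and open points did not, and an asterisk marks the 8 lists that passed with an estimated correlation. Acute phase genes have the lowest median at −0.78, and the unfolded protein and integrated stress response has the highest at 0.30.

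Enzymes linked to lactate and lactylation changed little. Ldha, which interconverts pyruvate and lactate, went from 507 ± 1.76 to 468 ± 2.36 FPKM (SD, n = 3). Its log2 fold change by TMM-scaled counts was −0.19 (SE 0.02, edgeR adjusted p = 2e-10), a larger fall than that of the FPKM means. Ldhb was near the lower limit of the tested genes at 1.53 and 2.12 FPKM and did not pass (log2 fold change 0.40, SE 0.21, adjusted p = 0.131), although it did in the limma fits. Sirt3, a mitochondrial deacylase, rose 1.19-fold. The log2 fold change of Ep300, an acyltransferase, was 0.14 (SE 0.05, adjusted p = 0.0322), and it did not pass without sedentary replicate 1 (0.0875), sedentary replicate 2 (0.0844), exercise replicate 2 (0.299) or exercise replicate 3 (0.0813), nor by DESeq2 (0.152) or most limma fits. The list of lactylation-related enzymes had 7 of 21 members higher and 3 lower (median 0.10, adjusted p = 0.398), and that of glycolysis and lactate handling had 11 of 30 higher and 8 lower (median 0.02, or 0.00978 to 0.0317 with 1 library left out, adjusted p = 0.38). Neither passed in any of the 21 alternatives in which lists were tested.

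Genes of gluconeogenesis and glycogen had 11 of 26 members higher and 6 lower, with a median of 0.04 (0.0254 to 0.0594 with 1 library left out, adjusted p = 0.00847), a call lost with an estimated correlation (adjusted p = 0.099). Pck1 and G6pc, enzymes of glucose production, rose 1.38-fold and 1.40-fold, and Igfbp1 fell (log2 fold change −0.72, SE 0.06). Oxidative phosphorylation genes had 21 of 72 members higher and 1 lower, with a median of 0.05 (adjusted p = 0.0332, and 0.545 with an estimated correlation), and the call ended without sedentary replicate 3 (0.0557), without exercise replicate 3 (0.0836) and at a mean FPKM of at least 5 (0.108). Ribosomal protein genes had 44 of 85 members higher and 2 lower, with a median of 0.08 (adjusted p = 0.00597, and 0.415 with an estimated correlation). Citric acid cycle genes had 7 of 25 members higher and 2 lower (median 0.04, adjusted p = 0.319), and the list passed in 9 of 21 alternatives. Amino acid catabolism genes had 9 of 40 members higher and 14 lower, with a median of −0.03 (adjusted p = 0.0327, and 0.138 with an estimated correlation), and hepatocyte markers had 10 of 31 higher and 15 lower, with a median of −0.04 (−0.0481 to −0.0217 with 1 library left out, adjusted p = 0.00597, and 0.295 with an estimated correlation). The medians of these last 2 lists changed sign under other scalings. Of 21 alternatives, the gluconeogenesis list passed in 13, amino acid catabolism in 7 and hepatocyte markers in 11, 1 of which, quantile normalization, gave the opposite direction (median 0.0846, adjusted p = 0.00676).

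Male-biased liver genes had 17 of 32 members lower, 12 higher and a median of −0.14 (adjusted p = 1.89e-10), a call lost with an estimated correlation (adjusted p = 0.0937) and after quantile normalization (0.154). Moxd1 led the falls, and the urinary protein genes Mup17 and Mup15 had log2 fold changes of −1.36 and −1.05, although reads of this gene family are hard to tell apart. Female-biased genes had 6 of 14 members higher and 3 lower, with a median of 0.07 (adjusted p = 0.000496, and 0.0644 with an estimated correlation), led by Cyp4a10, which is also in the PPAR-alpha list, and the list passed in 12 of 21 alternatives. Growth hormone and IGF axis genes had 8 of 15 members lower and 2 higher, with a median of −0.12 (adjusted p = 0.0134, and 0.146 with an estimated correlation). Cish and Onecut1 fell most there, and the repressor gene Bcl6 rose 1.91-fold. Liver endothelial markers had 13 of 24 members higher and none lower, with a median of 0.20 (adjusted p = 0.0134), a call lost with an estimated correlation (adjusted p = 0.107). At a mean FPKM of at least 5 these last 2 calls ended as well (adjusted p = 0.464 and 0.0847).

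Across the 37 tested lists, 22 passed with the preset correlation, 12 of them higher and 10 lower, and 8 passed with an estimated correlation. Fry called 32 lists in 1 direction on balance and all 37 for change in either direction. Adjusted over the list alone, the counts of members were the same in 21 lists and differed by at most 2 in the other 16. Stellate cell and fibroblast markers (8 of 20 higher, 4 lower, adjusted p = 0.619), red blood cell markers (4 of 7 lower, none higher, 0.245) and adipocyte markers (2 of 7 higher, 3 lower, median 0.05, or 0.0314 to 0.0814 with 1 library left out, mean −0.03, 0.665) did not pass as lists. Red blood cell markers passed in 8 of 21 alternatives, all of them fits of log2 FPKM or TPM, among them limma on log2(FPKM + 1) (0.0108). Markers of T cells, B cells, bile duct cells and skeletal muscle had at most 4 tested genes each and were not tested as lists. Among them the cholangiocyte marker Spp1 fell 2.09-fold. The list of nuclear-retained RNA and histones had 3 tested genes, too few for a list test, of which H2afx and H2afz rose (log2 fold changes 0.67 and 0.11) and Snhg11 did not pass, and its summed counts were 1515 to 1591 in the sedentary and 1774 to 1825 in the exercise libraries. Both tested acinar genes fell, Amy2a5 and Cela1 (log2 fold change −0.54, SE 0.10). The 4 Y-linked transcripts were at 2.87 FPKM or more in each of the 6 libraries.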

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

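DESeq2, limma on log2(FPKM + 1), edgeR without TMM, the test against a 1.2-fold change, the length and GC offset and the summed libraries were chosen after seeing the data. Leaving out 1 library left 3402 to 3491 genes past the threshold, against 3913 with all 6. Of the 30 genes named as the 15 highest and the 15 lowest, all stayed past the threshold in each of the 6 such fits except Cox7a1 without exercise replicate 1. Across 21 alternatives the acute phase, interferon, cholesterol, PPAR-alpha, fatty acid oxidation, heat shock and unfolded protein lists kept their direction and their call. The acute phase median lay between −0.82 and −0.62. The ketone body, xenobiotic, macrophage and ribosomal protein lists also kept both in these 21, but their calls were lost with an estimated correlation. Of the named genes' fold changes under all alternatives, 5151 stayed on their side of the threshold, 609 fell below it, 43 rose above it and 4 changed sign with a call in at least 1 of the fits compared. The list medians gave 663, 50, 42 and 20. Changes of sign without a call in either fit are among the 5151 and the 663, and include medians of the circadian clock, extracellular matrix, pericentral, periportal and adipocyte lists.

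In edgeR the scaling moved the split of calls. Genes lower in exercise were 1952 with TMM, 1203 without it (3537 higher) and 1429 without the 20 most abundant genes (2918 higher). The limma fits change the measure and the test as well. Scaling moved their split too, since quantile normalization of log2(FPKM + 1) took it from 2868 higher and 1099 lower to 1727 and 1465. The part of the measure and the test was not tested. In the other limma fits the lower genes were 915 on the TPM scale (3716 higher), 1096 with a pseudocount of 0.1 or with sample weights, 1099 with a pseudocount of 0.5 or of 1, 1081 without a variance trend and 1103 with robust limma. The median log2 fold change of all genes was at most 0.0956, on the TPM scale. Genes changed at least 2-fold were 94 in the edgeR fit. They were 243 without a filter (54 higher, 189 lower) and 52 at a mean FPKM of at least 5 (9 higher, 43 lower), where more or fewer genes were tested. On the pseudocount scale, which shrinks the folds of low genes, they were 47 in the limma fits (31 lower), 52 on the TPM scale (30 lower) and 50 after quantile normalization (12 higher, 38 lower), with 42 lower at a pseudocount of 0.5.

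The test against a 1.2-fold change called 653 genes, 239 higher and 414 lower. With 1 summed library per group, an assumed variation of 0.1 left 179 genes (50 higher, 129 lower) and one of 0.2 left 23 (5 higher, 18 lower), all of them changed at least 2-fold. DESeq2 called 2512 genes, 1272 higher and 1240 lower, and all 2512 were among the 3913. The cause was not tested. With an estimated correlation 8 of the 37 lists passed in place of 22. For ketone body, gluconeogenesis, female-biased and endothelial genes the estimate was −0.103, −0.0176, −0.0341 and −0.0340, below the preset 0.01. For amino acid catabolism and secreted hepatokines it was 0.00347 and 0.000484, below it as well. A higher correlation was thus not why those calls were lost. The offset for length and GC content left 3880 genes, 3545 of them shared.

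The list medians that changed sign with a call lay near 0, and the cause was not tested. Amino acid catabolism was at 0.0425 and 0.0424 with pseudocounts of 0.1 and 0.5, 0.0423 in the limma fits (0.0418 with sample weights), 0.0767 on the TPM scale, 0.0186 without the 20 most abundant genes and 0.0468 without TMM. Hepatocyte markers were at 0.0376 with both pseudocounts, 0.0375 in the limma fits (0.0367 with sample weights), 0.0412 without TMM, 0.0721 on the TPM scale, 0.0130 without the 20 most abundant genes and 0.0846 after quantile normalization. Female-biased genes were at −0.0106 without a filter. The log2 fold change of Hagh was 0.0134 and the log2 fold change of Alas2 was 0.0045 on the TPM scale. After quantile normalization, the log2 fold change of Fga was 0.10 and the log2 fold change of Ambp was 0.14.

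Whether the replicate numbers of the titles pair the libraries could not be decided. Deviations within a group were little more than counting noise for genes under 2000 reads, so paired libraries could also correlate near 0. Deviations of same-numbered libraries from their group means correlated at −0.0365, −0.0252 and −0.0300 across genes, and no library correlated best with its own number. A fit with the replicate block called 3846 genes, 3827 of them shared with the fit without it. Depth was not varied, and at this depth a count of 0 allows up to 3 reads per library. In simulated data at this depth and the spread of these libraries, with few genes changed, 90% of genes changed 1.5-fold were recovered. That share does not describe a wider spread between animals.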

Other observations

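The tests of the acinar transcripts and of the neutrophil genes in this part were chosen after the values were seen.

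Immediate-early genes split, with 11 of 25 members higher and 9 lower (median 0.06, or 0.0390 to 0.0747 with 1 library left out, mean −0.08, camera adjusted p = 0.708). Fos and Klf10, a growth-factor-induced repressor, had log2 fold changes of 1.76 and 0.92, while Gadd45g, Myc and Egr1 had −1.89, −1.86 and −1.35. Circadian clock genes were also split, 7 of 19 higher and 6 lower (median 0.01, or −0.0236 to 0.0344 with 1 library left out, mean −0.03, adjusted p = 0.708), with Nr1d1 at 0.38 and Usp2 at −0.61. Secreted hepatokine genes had 12 of 27 members higher and 10 lower. Their median was 0.09 (0.0261 to 0.174 with 1 library left out) while the mean was −0.02 and camera's direction was down (adjusted p = 0.0327, and 0.138 with an estimated correlation), and the call held in 8 of 21 alternatives, being lost without exercise replicate 1 (0.0691) among others. Orm2 and Hamp, the iron regulator hepcidin, fell there, and Angptl8 and Fgf21 rose.

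Genes of the pericentral and periportal zones of the liver lobule did not move as lists, with 11 of 28 higher and 6 lower (adjusted p = 0.879) and 11 of 29 higher and 15 lower (adjusted p = 0.708). Proliferation genes had 5 of 10 tested members lower and none higher (median −0.41, adjusted p = 0.0748), among them the replication genes Mcm6, Mcm2 and Mcm3 at −0.74, −0.70 and −0.67, and the list passed in 11 of 20 alternatives. Extracellular matrix genes had 5 of 23 members higher and 8 lower (median 0.01, or −0.0423 to 0.0132 with 1 library left out, mean −0.12, adjusted p = 0.319), with Col15a1 at −1.25 and fibronectin (Fn1) at −0.48. Among genes outside the rule for named genes, chosen after their values were seen, Cyp3a41a had 8, 9 and 8 reads in the exercise libraries and none in the sedentary ones. Entpd4 had 105.85 and 53.07 estimated counts in exercise replicates 2 and 3 and none in the other 4 libraries.

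The libraries of a group differed by little more than counting noise among genes with under 2000 reads in a pair, although the design text gives 3 mice per group. Among genes with 2000 reads or more they differed by more, with a mean chi-square of 2.62 to 3.46. Genes that usually vary between animals (acute phase, interferon, immediate-early, clock and PPAR-alpha lists, 133 genes) had a mean within-group excess spread at percentile 66.83 of 10000 count-matched lists. Repeat libraries of 1 RNA sample or pool per group would give such a percentile. So would separate animals in which these genes vary no more than others, so the percentile cannot tell the 2 apart. Against repeat libraries, the column names carry 6 different numbers, and 3 separate mice with very alike livers were not tested and stay open. Such livers would have to be alike to a common biological coefficient of variation of 1.84%. The reads of 11 acinar genes in the sedentary libraries were 115, 135 and 109. These genes were picked because every sedentary library had reads of them and no exercise library did, so their likeness cannot decide this. If the libraries were repeats, the group differences could belong to the animals or the pool as well as to exercise.

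Acinar transcripts were higher in the sedentary libraries, and some were seen there alone. A change of amylase expression in the liver by itself would leave the other acinar genes at 50.4% sedentary reads, the share of all reads, but 66.6% of the 1102 reads of acinar genes without Amy2a5 were sedentary (exact binomial interval 63.7% to 69.4%), most of them from Cela1 with 159, 153 and 163 reads against 107, 112 and 121. Of 14 such genes with at least 3 reads, 10 had reads in each sedentary library and none in any exercise library, Ctrb1 with 16, 17 and 10 and Pnlip with 10, 17 and 5 among them. A small amount of pancreatic tissue in the sedentary material is a candidate source, and Cela1, Cela2a and Ctrl had reads in both groups. The 11 genes gave 115, 135 and 109 reads in the 3 sedentary libraries.

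Acute phase genes were lower in the exercise libraries. Scaling by a few very abundant genes moves all genes by 1 factor, and the median log2 fold change of all genes was at most 0.0956 in any alternative. That is too little for this fall. The list median was −0.73 with totals taken without the 20 most abundant genes, which adds little, since it could hardly have differed. Neutrophils in the sedentary liver would lower other neutrophil genes by as much as Lcn2 (−5.79), but the 5 with at least 20 reads had a median of −0.34, between −0.59 and 0.62. The granule protease gene Prtn3, which is not among those 5, had a log2 fold change of −3.21, so a small share of such cells or their precursors is not ruled out. An effect of training, an inflammatory state of the sedentary animals or a difference in handling could each give this pattern, and the design cannot part them, because no day, cage or sampling order is labelled.

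Of the 10 splits of the 6 libraries into 3 and 3, 1 split, the labelled one, called as many genes as the 3913 by edgeR. The highest of the other 9 called 0, with 115 to 167 genes at an unadjusted p under 0.05 (4695 in the labelled split), and limma called at most 1 gene in them. Those other splits hold libraries of both groups on each side. The group difference then enters their spread, so few calls were possible in them. With 10 splits the share cannot go under 0.1.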
